A study of Danio rerio with 7 samples.

How the data were processed

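Adult zebrafish hearts carrying the nppa:mCitrine reporter were cryoinjured and taken 7 days later, per the labels' protocols. The ventricles were dissociated, and mCitrine-positive cells, labelled as border zone cardiomyocytes, were sorted at 1 cell per well into multiwell plates. Libraries were made by SORT-seq with CEL-Seq2 chemistry, in which barcoded primers mark each cell and spike-in RNA is added to each well. The 7 plates fall into 3 wildtype and 4 hmga1a mutant plates, and the group of each plate was taken from its label. The submitters' processing notes name Seurat, a package for single-cell expression data, and give neither a version nor a role for it. The aligner, genome build, gene annotation and cell filters are not given in the sources used here.

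What was analysed is a deposited set of 8 gene modules, each a list of Ensembl zebrafish gene identifiers, and 8 deposited annotation charts, 1 per module. The module lists carry no values, so neither expression levels nor sequencing depth per plate are known from them, and no plate enters any test. How the modules were made, and in which plates their genes were higher or lower, is not given in the sources used here. The comparison of wildtype with hmga1a mutant plates that the labels imply, planned as an exact permutation test over plates, was therefore not made.

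In the annotation charts the authors give for each term the number of module genes in it, the annotated genes of the module and the matching numbers for a background. The fold enrichment in each chart is the authors' ratio of the share of module genes in the term to the share of background genes in it, per the file headers and checked on the values. The p-value and the Benjamini-adjusted p-value of each term are the authors' own, per the file headers. A further column of false discovery rates was not used because its number format was damaged. The column names are those that charts of the DAVID annotation tool carry, and the tool and its release are not stated. Listed terms had a p-value of at most 0.1 and at least 2 genes in the deposited charts. The backgrounds held 20385 annotated genes for biological processes, 20439 for cellular components, 19276 for molecular functions and 6895 for KEGG pathways, all more than the 4449 genes in the modules. Recomputing p with the conservative hypergeometric form used by DAVID (1 gene removed from each term) gave values within 1% of the deposited ones for 95.6% of the 834 terms.

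Identifiers were given symbols from a name table of 29201 zebrafish genes, and 3651 of the 4449 module genes (82.1%) had one. Of those symbols, 2211 (60.6%) were written in capitals, in the human style. Such symbols often lack the final a or b of zebrafish names, and 88 symbols stood on more than 1 identifier. Symbols were compared with the lists exactly, ignoring case. A RefSeq gene table of assembly GRCz12tu served only for synonyms and for which genes neighbour each other.

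Before the data were examined, 30 gene lists were fixed. Of these, 23 were pathways and complexes of heart muscle, energy metabolism, protein synthesis, proliferation, matrix and stress, and 7 were markers of other cell types that the sort could also hold. The lists covered 574 of the module genes. The 27 lists with at least 5 distinct genes in the modules were tested, and the markers of erythrocytes, thrombocytes and neural cells had too few. Each list was compared with each module by a two-sided Fisher's exact test against the genes of the other modules. The 216 p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and also over each list alone. Exact 95% binomial intervals (Clopper-Pearson) go with the share of a list in a module. They cover counting error only, and genes are not independent replicates of the animals, so the p-values describe the make-up of the modules and not the spread between fish. Whether a list was spread over the modules as all genes were was tested by 100000 permutations of the module labels over genes, with a chi-square statistic and Benjamini-Hochberg adjustment over lists. Pairs of genes whose symbols differ only in a final a or b were tested for lying in the same module by 100000 permutations, two-sided. The smallest p these permutations can give is 1e-05 before adjustment in the spread test. Terms of the annotation charts were counted at a Benjamini-adjusted p under 0.05, and sorted into keyword groups fixed in advance, without a new test.

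The genes named were chosen by a rule fixed in advance. It names 26 genes of the border zone, contraction, proliferation and metabolism wherever they lie. For every list over-represented in a module it names up to 8 members, the first in the deposited order. For each module it names the 5 terms with the lowest adjusted p having at least 3 genes and up to 4 genes of the first, and for modules without an over-represented list up to 5 of the first named genes. For the a and b pairs it names up to 6 in the same module and up to 6 split ones, in alphabetical order among pairs of the fixed lists. Other members are named where they do another job than their list's name says, make up a small count or serve as examples of one, and those were chosen after their place was seen.

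The scripts were tested on simulated data, with lists drawn at random from the 4449 genes. Lists of 30 genes drawn with a 4-fold weight on module 7 were called there in 20% of 20 simulations, and lists of 10 genes with an 8-fold weight in 25%. At most 0.0647% of the other list and module pairs were called. The spread test called 45% of lists of 30 genes with the 4-fold weight and 5% of random lists. The pair test called 95% of draws with 25% of the 64 pairs forced together and 2.5% with none forced. A missing call for a short list is therefore weak evidence.

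Alternatives covered the background, synonyms, unnamed genes, the ribosomal and mitochondrially encoded genes, each module in turn, a and b copies, genes on several lists, the minimum list size and the threshold. Others covered the statistic of the spread test, the choice of pairs, and the threshold, gene minimum and adjustment of the term counts. Alternatives chosen after seeing the data covered symbols without a final a or b, the first ascending run of identifiers in each module, list members with another job, pairs of lower-case symbols, and distinct identifiers per term. The other assays that the series' design text names were not analysed here. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.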

Results

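Heart muscle cells next to a cryoinjury were sorted from adult zebrafish by nppa:mCitrine, a reporter of the natriuretic peptide gene that border zone cardiomyocytes switch on, 7 days after injury. Cells came from 3 wildtype plates and 4 plates of fish mutant for hmga1a, which encodes a DNA-binding protein of the high mobility group. The labels set the plates up to ask how border zone cells differ when hmga1a is lost. The deposited data analysed here divide 4449 genes over 8 modules of 1543, 600, 357, 475, 494, 438, 379 and 163 genes, in the order of their numbers, and no gene lay in more than 1 module. The module lists carry no values per plate or cell, so depth and replicate error are not known from them, and no gene can be called higher or lower in either genotype.

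The targeted gene, hmga1a (ENSDARG00000028335), lay in module 5, and its paralogue hmga1b (ENSDARG00000070951) in module 4. Module 5 also held nppa (ENSDARG00000052960), the gene behind the reporter, PCNA, a clamp of DNA replication, and CPT1B, which brings fatty acids into mitochondria. The related peptide gene nppb lay in module 2 together with the proliferation marker mki67, and xirp1, an actin-binding protein of the intercalated disc, lay in module 4. The contractile and calcium genes MYL7, tnnc1a and atp2a2a lay in module 7 with the glycolytic gene GAPDH, while HK1, the first enzyme of glycolysis, and PPARGC1A, a regulator of mitochondrial content, lay in module 6. Ignoring case, the symbol myh6 stood on 2 identifiers. Lower-case myh6 (ENSDARG00000090637), the name of an atrial myosin heavy chain, lay in module 6, and capitalised MYH6 (ENSDARG00000079564) lay in module 4. Which zebrafish heavy chain the capitalised symbol stands for is not known, so it may be another gene than the atrial one. Of the 26 genes followed throughout, 15 were in a module, and myh7, runx1 and ldha were in none. The other 8 (vmhc, mustn1b, ankrd1a, desmb, fosl1a, junbb, pkma and ryr2b) were not symbols of the name table, so their place could not be read by exact symbol. Without the final a or b, FOSL1 and JUNB lay in module 1 and RYR2 in module 4, and which copy each identifier stands for is not known.

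Over all lists, 13 of the 216 list and module pairs were over-represented and 12 were under-represented (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted p under 0.05). Adjusted over the list alone, 13 were over-represented and 15 under-represented. The 3 further ones were nuclear respiratory chain genes in modules 3 and 6 and cytosolic ribosomal proteins in module 3. Both counts changed greatly with every gene of the name table as background and without module 7, as given in the closing section.

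**Figure D1:**
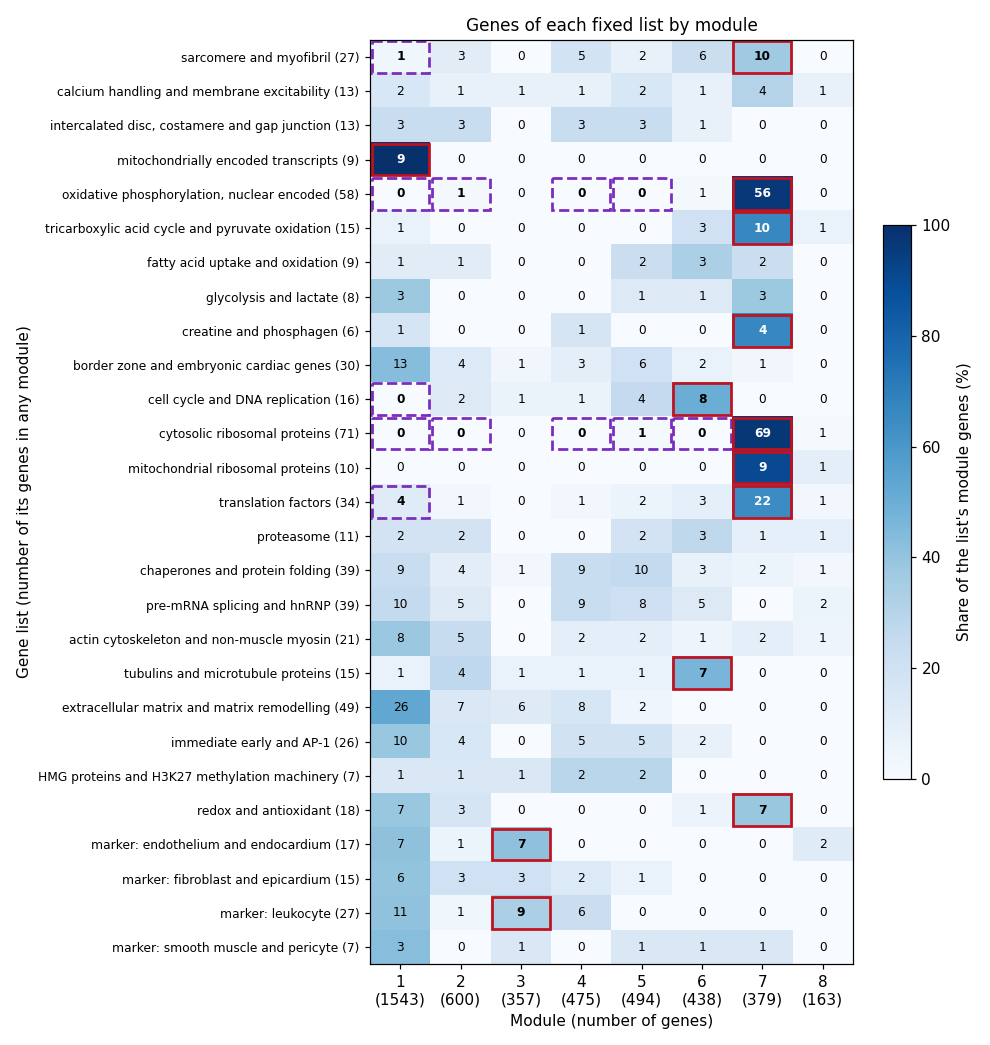
Number of genes of each fixed list (rows, with the number in any module) in each module (columns, with the module's number of genes). Shading gives the share of the list in percent, solid frames mark the 13 over-represented and dashed frames the 12 under-represented pairs by Fisher's exact test, and 8 of the 13 stand in module 7.

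Module 7 gathered the machinery of protein synthesis and oxidative energy. Of the 71 cytosolic ribosomal proteins in any module, 69 lay there, 11.4 times the number expected (97.2%, exact 95% interval 90.2% to 99.7%). Of the 58 nuclear-encoded genes of oxidative phosphorylation, 56 lay there, 11.3 times the number expected (96.6%, interval 88.1% to 99.6%). The adjusted p was 1.68e-71 and 3.81e-57 (Fisher's exact test). RPL28, RPL23A, RPL38, RPL12, RPL7, RPL15, RPS15A and RPL21 were among the ribosomal genes, and ATP5PO, ATP5PB, ATP5MG and atp5mc3b of the ATP synthase, UQCRFS1 and UQCRB of complex III, NDUFB8 of complex I and cox4i1l of complex IV were among the respiratory ones. The exceptions were few. The 2 ribosomal names elsewhere, RPL7L1 in module 5 and rps19bp1 in module 8, are not structural proteins of the cytosolic ribosome, and the 2 respiratory genes elsewhere were cox6a1 in module 2 and higd1a in module 6.

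The same module held 9 of 10 mitochondrial ribosomal proteins (10.6-fold, adjusted p = 7.21e-08, Fisher's exact test), among them MRPL41, MRPL19, MRPS35, MRPL23, MRPL4, mrps18c, mrpl58 and mrpl52. MRPL32 was the exception, in module 8. It also held 22 of 34 translation factors (7.60-fold, adjusted p = 2.51e-14, Fisher's exact test), including the initiation factors eif4a1b, eif4eb and EIF3G, eif5a, the elongation factor eef1a1l1 and the poly(A)-binding proteins pabpc1a and pabpc1b. The list also named naca, a chaperone of nascent chains. Members whose job is to restrain translation were in it too: eif4ebp1 and EIF4EBP2, which block the cap-binding protein, were among the 22, and the eIF2 kinases eif2ak2, EIF2AK3 and eif2ak1 lay in modules 1 and 8, with EEF2K and EIF4EBP3 in module 6. Of 15 genes of the citric acid cycle and pyruvate oxidation, 10 lay in module 7 (7.83-fold, adjusted p = 1.13e-06, Fisher's exact test), among them IDH2, DLST, SDHC and MDH2 of the cycle and pdha1a, PDHB, DLAT and PDHX of pyruvate dehydrogenase. PDK4, a kinase that switches pyruvate dehydrogenase off, lay in module 6 with ogdha and IDH3G, PDP2, a phosphatase that switches it on, lay in module 1, and SUCLG2 lay in module 8.

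Contractile genes were split. Module 7 held 10 of 27 sarcomere genes, 4.35 times the number expected (37.0%, interval 19.4% to 57.6%, adjusted p = 0.00109, Fisher's exact test). They were thin-filament and light-chain genes such as tnnc1a, tnni1c, tpm4a, actc1a, MYL7 and cmlc1, with ldb3a of the Z-disc and KLHL31. Module 6 held 6 of the 27, among them MYBPC3, and module 4 held 5, among them the myosin heavy chains MYH6, myh7ba and myh7bb, and neither count passed the test. The list names titin by numbered symbols, which TTN in module 4 did not match. Titin is therefore missing from these counts and from those without a final a or b. Only 1 sarcomere gene, tnnt2c, lay in module 1, the module with most genes (0.107-fold, adjusted p = 0.00449, Fisher's exact test). With capitalised symbols matched without a final a or b, chosen after the lists were seen, PDLIM3, FLNC, KLHL40 and XIRP2 joined it there, 5 of 39 in all, and module 6 passed with 10 of 39 (2.60-fold, adjusted p = 0.0296, Fisher's exact test). For module 1 the call held (0.370-fold, adjusted p = 0.0296, Fisher's exact test, against 0.00135 to 0.66 over all alternatives). Phosphagen genes, which buffer ATP in muscle, were in module 7 in 4 of 6 cases, AK1, ckma, ckmb and GAMT (7.83-fold, adjusted p = 0.00813, Fisher's exact test). Redox genes were there in 7 of 18 cases (4.57-fold, adjusted p = 0.00578, Fisher's exact test). These were fth1a, PRDX1, TXN, selenow1, SOD2, prdx5 and gstk1. As many, 7, lay in module 1: the stress-induced HMOX1 and SQSTM1, the metallothionein MT1X, the thioredoxin inhibitor TXNIP, txnb, msrb2 and a further identifier of prdx1.

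The 12 under-represented pairs were largely the mirror of module 7. Cytosolic ribosomal proteins were fewer than expected in modules 1, 2, 4, 5 and 6, nuclear respiratory genes in modules 1, 2, 4 and 5, and translation factors in module 1, where 4 of 34 lay (0.339-fold, adjusted p = 0.0313, Fisher's exact test). That last call was lost in 4 of 18 alternatives (adjusted p 0.00607 to 1 over all of them, Fisher's exact test).

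Module 6 held 8 of the 16 cell cycle genes, 5.08 times the number expected (50.0%, interval 24.7% to 75.3%, adjusted p = 0.00126, Fisher's exact test). They were CDK1 and its partner cks2, the replication genes GINS4 and POLA2, the spindle and kinetochore genes NUSAP1, TTK and cenph, and cdca3. PCNA, RRM2, SMC4 and the tubulin tubb4b lay in module 5, anln and mki67 in module 2, CCNB1 in module 3 and bub1 in module 4, and none lay in module 1 (adjusted p = 0.0223, Fisher's exact test), a call lost in 3 of 18 alternatives (0.00538 to 0.641 over all of them). Module 6 also held 7 of 15 tubulin and microtubule genes (4.74-fold, adjusted p = 0.0042, Fisher's exact test), namely mapre1b, STMN1, tuba8l2, tuba5, MAP1S, TUBG1 and MAP4K5. MAP4K5 is a kinase of stress signalling and no microtubule protein; without it the count was 6, with adjusted p = 0.0151 (Fisher's exact test). With only the first ascending run of identifiers in each module, 3 of the 6 cell cycle genes left were in module 6 (4.91-fold) and the adjusted p was 0.132, against 8.53e-05 to 0.132 over all alternatives.

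All 9 mitochondrially encoded transcripts in any module lay in module 1, 2.88 times the number expected (100%, interval 66.4% to 100%, adjusted p = 0.0014, Fisher's exact test). They were MT-ND1, MT-ND2, MT-ND3 and MT-ND4 of complex I, MT-CYB of complex III, MT-CO1, MT-CO2 and MT-CO3 of complex IV and MT-ATP6 of the ATP synthase. None of the 58 nuclear-encoded partners lay there, against 20.1 expected (adjusted p = 7.97e-10, Fisher's exact test). As 56 of the 58 lay in module 7, that absence largely restates their place there and is no separate evidence. The transcripts share 1 genome and are not independent of each other. Matrix genes were unevenly spread over the modules (adjusted p = 0.0114, permutation test; 0.0599 in the first runs of identifiers alone, against 0.00012 to 0.0599 over all alternatives), and 26 of 49, among them COL1A1, COL4A1, SPARC and AGRN, lay in module 1, where the adjusted p of 0.0739 missed the threshold. Modules 6, 7 and 8 held none of the 49.

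Module 3 held markers of other cell types than cardiomyocytes. Of 27 leukocyte markers, 9 lay there, 4.15 times the number expected (33.3%, interval 16.5% to 54.0%, adjusted p = 0.00286, Fisher's exact test). They were the complement genes c1qa and c1qb, the macrophage receptor marco, the transcription factor spi1a, the cytokine tnfa, cyba of the NADPH oxidase, CORO1A, nkl.2 and arhgdig. Of 17 endothelial markers, 7 lay there, 5.13 times the number expected (41.2%, interval 18.4% to 67.1%, adjusted p = 0.00322, Fisher's exact test). They were flt1, robo4, rasip1, ramp2, sox18, she and ERG. A further 11 leukocyte and 7 endothelial markers lay in module 1, which holds 34.7% of all genes, and there neither list was over-represented. Of the 69 markers of other cell types in the modules, 20 were also on a list of another kind, 13 of them among the 15 fibroblast and epicardial markers. In the first runs of identifiers alone 1 endothelial marker was left in module 3 (2.32-fold), and the adjusted p was 0.867, against 9.54e-06 to 0.867 over all alternatives.

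Modules 2, 4, 5 and 8 had no over-represented list. Their first named genes were SLC40A1, matr3l1.1, srrm1, FRMD6 and UBB in module 2, TTN, SYPL2, MYCBP2, STT3B and LAMB2 in module 4, STRN3, PTPRA, kcnh6a, HSD11B2 and zfand5b in module 5, and slc6a22.1, TNFRSF21, ADSS2 and ASPA in module 8. Chaperones and splicing factors were unevenly spread (39 genes in each list, adjusted p = 0.0344 and 0.0369, permutation tests) without 1 module past the threshold. Of the chaperones 10 lay in module 5, among them HSPA8, HSPA9 and FKBP5, and 9 in module 4, among them BAG3, HSPB8 and DNAJB5. The uneven spread of the chaperones was lost with a likelihood-ratio statistic (adjusted p = 0.0979, permutation test, against 0.0311 to 0.0979 over all alternatives), with a and b copies as 1 gene (0.0591) and in the first runs (0.0595). That of the splicing factors was lost in the first runs (0.0595, against 0.00945 to 0.0595).

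In all, 16 of the 27 lists were unevenly spread by the permutation test, and 9 of these in the first runs of identifiers alone. The border zone and embryonic cardiac genes were not called: their 30 members lay 13 in module 1, 6 in module 5, 4 in module 2, 3 in module 4, 2 in module 6 and 1 each in modules 3 and 7 (adjusted p = 0.578, permutation test). With symbols matched without the final a or b, that list had 45 genes, 23 of them in module 1 (1.47-fold, adjusted p = 0.155, Fisher's exact test). Its spread was still not called (adjusted p = 0.354, permutation test). Calcium handling genes (13, adjusted p = 0.225), intercalated disc genes (13, 0.428), fatty acid oxidation genes (9, 0.181) and glycolytic genes (8, 0.207) were not called either by the permutation test. Nor were proteasome subunits (11, 0.412), actin cytoskeleton genes (21, 0.803), immediate early genes (26, 0.332), high mobility group and H3K27 methylation genes (7, 0.467), fibroblast and epicardial markers (15, 0.467) and smooth muscle markers (7, 0.927). Matched without the final a or b, the glycolytic list had 20 genes and the immediate early list 42, and both were called (adjusted p = 0.00345 and 0.0345, permutation tests, against 0.00345 to 0.454 and 0.0345 to 0.478 over all alternatives). The histone methyltransferase genes ezh1 and EZH2 lay in modules 2 and 3, HMGA2 lay with hmga1a in module 5, cbx7a lay in module 1, and kdm6bb, a demethylase, lay with hmga1b in module 4. The test called 45% of simulated lists of 30 genes with a 4-fold weight on module 7, so a moderately uneven spread of such lists could be missed. Of the lists too short to test, 2 erythrocyte markers lay in modules 1 and 8, gata1a and si:ch211-5k11.8, the thrombocyte marker GP1BB lay in module 1, and no neural marker lay in any.

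Zebrafish keep many duplicated genes, whose copies carry the endings a and b. Symbols that differ only in that ending formed 64 pairs, not all of them duplicates, and 24 lay in the same module (37.5%, exact 95% interval 25.7% to 50.5%), against 18.7% expected from shuffled module labels (two-sided permutation p = 0.00082). Pairs in the same module included atp5if1a and atp5if1b, inhibitors of the ATP synthase, and the ATP synthase genes atp5mea and atp5meb. Others were the creatine kinases ckma and ckmb, cd74a and cd74b of antigen presentation, and marcksl1a and marcksl1b. The complement genes c1qa and c1qb also lay together and are subunits of the same protein, not copies of each other. Split pairs included hmga1a and hmga1b (modules 5 and 4), hnrnpa0a and hnrnpa0b (modules 6 and 4), ARPC1A and ARPC1B (modules 7 and 4) and CPT1A and CPT1B (modules 4 and 5), the last 2 being older genes that other vertebrates also have. Of the split pairs by name, cyba with cybb (modules 3 and 4) and eif5a with eif5b (modules 7 and 6) are different proteins. A further test left out pairs with a capitalised symbol, and c1qa with c1qb, cyba with cybb, eif5a with eif5b and nppa with nppb. Of the 40 pairs left, 16 were in the same module (40%, permutation p = 0.0029). Whether each of the 40, such as tnfrsf1a with tnfrsf1b, is a pair of copies was not checked.

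The annotation charts gave a wide range of terms per module. The authors' deposited table lists 83 terms at an adjusted p under 0.05 for module 7, 9 each for modules 1, 3 and 6, 5 for module 5, 1 for module 8 and 0 for modules 2 and 4. For modules 2 and 4, the authors' deposited table holds 51 and 43 terms at an unadjusted p under 0.05. By keyword, 30 of the 83 terms of module 7 in the authors' deposited table fall under oxidative energy, 24 under translation, 4 under glycolysis and glucose and 3 under muscle and heart. A term can fall in more than 1 group, and the oxidative energy group takes in every term that names mitochondria. Leading module 7 in the authors' deposited table are structural constituent of ribosome (78 genes, 33.6-fold, adjusted p = 3.03e-98; MRPL23, RPL5, RPS26 and RPL9 first), translation, ribosome as a cell component and as a pathway, and the cytosolic large ribosomal subunit.

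**Figure D2:**
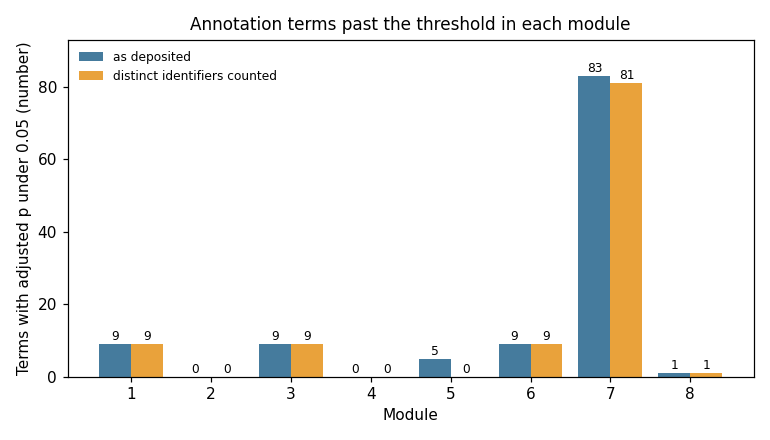
Number of annotation terms with an adjusted p under 0.05 in each module, as the authors' deposited table gives them and after counting the distinct gene identifiers listed for each term. The recount left the annotated totals and background counts of the charts unchanged, so it can only raise p. Module 7 has 83 and 81 terms, and the 5 terms of module 5 fall to 0.

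For module 1 the authors' deposited table leads with membrane (434 genes, 1.22-fold, adjusted p = 8.27e-05; plxnb2a.1, mhc2dab, ITGB1 and creb3l3a first). ECM-receptor interaction (21 genes, 3.38-fold), sphingolipid metabolism (15 genes, 3.75-fold) and lysosome as a pathway (27 genes, 2.54-fold) and as a component (26 genes, 2.63-fold) follow in the authors' deposited table. For module 3 the authors' deposited table leads with membrane terms (120 genes in membrane, 1.44-fold, adjusted p = 0.000112; npdc1a, irgf1, abcc2 and tnfa first), integral component of membrane and plasma membrane among them. Chemotaxis (8 genes, 11.2-fold) and cytokine-cytokine receptor interaction (13 genes, 3.90-fold) come next in the authors' deposited table. For module 6, nucleus leads the authors' deposited table (131 genes, 1.67-fold, adjusted p = 1.71e-08; FBXO38, TCEA2, FUBP1 and zgc:112977 first), with nucleotide binding, cytoplasm, kinase activity and ATP binding after it. Spindle, the cell division term of module 6, has 7 genes there (7.03-fold, adjusted p = 0.0338 in the authors' deposited table). For module 8 the term past the threshold in the authors' deposited table is endoplasmic reticulum (13 genes, 3.41-fold, adjusted p = 0.044; TMEM208, PGAP2, TRAPPC6A and TMED4 first). Endoplasmic reticulum membrane, sprouting angiogenesis, magnesium ion binding and nucleotide binding follow there without passing.

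No term passed for modules 2 and 4. Salmonella infection leads the authors' deposited table for module 2 (20 genes, adjusted p = 0.0549; PIK3CA, flna, CYTH1 and MAPK14 first), before endocytosis, C-type lectin receptor signaling, insulin signaling and progesterone-mediated oocyte maturation. Cytoplasmic vesicle leads the authors' deposited table for module 4 (13 genes, adjusted p = 0.251; SCAP, RND3, rac2 and rusc1 first), before blood coagulation, protein transport, SNARE complex and myosin complex.

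All 5 terms of module 5 count more genes than the identifiers listed for them, and UGT1A1 is in each. They are steroid hormone biosynthesis, porphyrin metabolism, cytochrome P450 drug metabolism, pentose and glucuronate interconversions, and ascorbate and aldarate metabolism, each at an adjusted p of 0.0363 in the authors' deposited table. For steroid hormone biosynthesis the authors' deposited table counts 9 genes but lists 3 identifiers, those of HSD17B12, UGT1A1 and HSD11B2. Pentose and glucuronate interconversions counts 7 genes and lists 1, UGT1A1, an enzyme that attaches glucuronic acid, in the authors' deposited table. With distinct identifiers counted, chosen after the lists were seen, no term of module 5 passed. The recomputed p was 0.554 to 0.807 for the 3 terms with 2 or 3 identifiers, and with 1 identifier it is 1 by construction. Only the module's genes in each term were recounted, while the annotated totals and the background counts stayed as in the charts. The recount can therefore only raise p, and it shows how far the terms rest on the repeated counts, not whether they are enriched. Ascorbate and aldarate metabolism too counts 7 genes and lists only UGT1A1 in the authors' deposited table. Why 1 identifier was listed there for 7 counted genes was not tested.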

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

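Alternatives chosen after seeing the data are the first ascending runs, the symbols without a final a or b, the list members with another job, the lower-case pairs and the distinct identifiers. The 25 called list and module pairs were tested again in 432 pairings with an alternative. None reversed, 408 kept their call and 24 lost it. The 13 over-represented pairs numbered 11 to 16 under all alternatives but 2: 34 with every gene of the name table as background, which held all 13, and 5 without module 7, which holds 8 of them. The 12 under-represented pairs numbered 2 with the name table as background, 7 without ribosomal and mitochondrially encoded genes, 1 without module 7 and 5 at an adjusted p under 0.01, and 10 to 13 under the others. Without module 7, 9 of the 12 could not be tested, since 2 ribosomal and 2 respiratory genes were left. Sarcomere genes and translation factors in module 1 lost their call (adjusted p = 0.11 and 1, Fisher's exact test). For translation factors, module 7 held 22 of the 34, so leaving it out lowered the number expected in module 1. Their fold there was 0.339 with all modules and up to 0.879 over the alternatives, so that shortfall largely mirrored module 7. For sarcomere genes the cause was not tested. Without the ribosomal genes and at the stricter threshold the fall follows from construction. With the name table, genes of no module joined the background, so each module was by construction a smaller share of it. How much of the fall this made was not tested. Unevenly spread lists numbered 16, and 15 to 18 under every alternative but the first runs. The 18, with symbols matched without a final a or b, added the glycolytic and immediate early genes. In the first runs alone, 9 of the 16 were called. The 7 lost there were mitochondrially encoded transcripts, phosphagen, cell cycle, chaperone, splicing, matrix and endothelial genes. For the mitochondrially encoded ones all 9 were kept and the unadjusted p was 0.0209 against 0.0232 (permutation tests), so the adjustment over lists took the call; for the others the cause was not tested. The share of pairs in the same module lay between 34.4% and 41.5% and passed the test under each alternative run.

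Where 116 annotation terms passed the threshold, 330 passed when the adjustment ran over the deposited terms alone, which were already selected by p. That setting gave 60 terms for module 1, 12 for module 2, 43 for module 3, 6 for module 4, 32 for module 5, 63 for module 6 and 2 for module 8. At an adjusted p under 0.01 modules 1 and 3 kept 5 terms each, and modules 5 and 8 kept 0. With distinct identifiers, and the background counts of the charts unchanged, module 5 kept 0. No gene lay in more than 1 module, so leaving such genes out changed nothing. No paired analysis was possible because the deposited lists hold no values per plate, and leaving out each plate in turn was not run for the same reason.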

Other observations

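The tests of list symbols without a final a or b, of stress and other cell types, and of missing symbols were chosen after the lists were seen. The tests of function between runs and of neighbouring genes were written before their results. For neighbouring genes, the rule set beforehand counted a share at or below the median of shuffled labels against the explanation. The interval of the share used below is another rule.

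Many capitalised symbols lack the ending by which the fixed lists name the gene, and matching them without it filled several lists. Glycolysis then had 20 genes, and 7 lay in module 7, 4.11 times the number expected (adjusted p = 0.0102, Fisher's exact test). These were GAPDH, PGAM2, ENO3, TPI1, LDHB and both identifiers of the aldolase ALDOA. HK1, GPI, PFKM, PFKP and the aldolase ALDOC were in module 6, a count that was not over-represented (adjusted p = 0.208, Fisher's exact test), and GAPDHS was in module 5. Module 1 held 5, eno2, the regulators PFKFB3 and PFKFB4 and the transporters SLC2A1 and SLC16A3, and SLC16A1 and the regulator HIF1A were in modules 2 and 4. Of 39 sarcomere genes, 10 were then in module 6 (2.60-fold, adjusted p = 0.0296, Fisher's exact test), among them TNNC1, LMOD2 and MYBPC3. Of 50 matrix genes, 27 were in module 1 (1.56-fold, adjusted p = 0.0483, Fisher's exact test).

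Mitochondrially encoded and nuclear-encoded genes of the same respiratory complexes lay in different modules, 9 of 9 in module 1 and 56 of 58 in module 7. Stress from dissociation or sorting may raise some transcripts together, and would then place immediate early genes with the mitochondrial ones. Of 26 such genes 10 were in module 1 (odds ratio 1.18, 95% interval 0.477 to 2.77), which leaves it open. Transcripts of other cell types may be another source, but of 69 pooled markers 29 were in module 1 (odds ratio 1.37, interval 0.817 to 2.28), which leaves that open too. The design gives no biological grouping to set against them, and with lists of this size neither explanation is decided.

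Each deposited module list is made of 2 to 7 stretches in which identifiers ascend before starting again, and 1218 of the 4449 genes (27.4%) lay in later stretches. The stretches may have been joined from smaller groups with genes of different function. Within modules, the fixed lists fell unevenly on first and later stretches (permutation p = 0.0001, the smallest that 10000 permutations can give). Of 16 cell cycle genes 10 were in later stretches against 4.34 expected, of 49 matrix genes 25 against 15.1, of 15 fibroblast and epicardial markers 10 against 4.81, and of 39 chaperones 1 against 10.5, which were the 4 lists past an adjusted p of 0.05. Of the fibroblast and epicardial markers, 13 are also on a list of another kind, so the 4 lists are not separate signals. A candidate explanation on the technical side is annotation status. Identifiers without a symbol were 3.22 percentage points more frequent in later stretches of the same module (95% interval from the spread of the permutations 0.509 to 5.93, permutation p = 0.0187). Over all modules the shares were 21.3% against 16.7%. Both the lists and the missing symbols thus differed between stretches. Neither result shows how the stretches arose, and neither excludes the other explanation.

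Genes that neighbour each other on a chromosome could share regulation and so a module. Of 393 neighbouring pairs in the RefSeq order, 65 were in the same module (16.5%, exact 95% interval 13% to 20.6%), against 18.7% expected from shuffled labels (two-sided permutation p = 0.303). The share lay below the expected one, which the rule set beforehand counted against an excess. It did so by less than its interval, so by the interval a small excess is not excluded, and a share above 20.6% is.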
